A study of Mus musculus with 5 samples.

How the data were processed

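The samples were laser-captured intervillus cells of the proximal jejunum of newborn mice at postnatal day 0. The intervillus region of the newborn intestine is the proliferating epithelium between villi, from which crypts later form. Per the labels' protocols, the tissue was held in methacarn for 1 h and embedded in paraffin, and areas were chosen on neighbouring sections stained for the proliferation marker Ki67. Ki67-negative areas were taken from mice with 2 floxed Dnmt1 alleles and the gut epithelial Cre driver VillinCre, and Ki67-positive areas from littermates with 1 floxed and 1 wild-type allele. Each sample gave between 2.3 and 33.3 ng of RNA, from which cDNA was made and amplified with the Ovation RNA-Seq V2 kit. Libraries were made from 300 ng of cDNA and read as single reads of 100 bp. There were 3 control libraries, numbered 1, 2 and 3, and 2 mutant libraries, numbered 4 and 6, each placed in its group by its title and genotype label.

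The authors deposited raw read counts per RefSeq transcript and, in a separate table with the same rows, FPKM values (fragments scaled to transcript length and library size). Per the submitters' processing notes, genome build mm9 and the program edgeR were used; the aligner, the counting program and all versions are not given in the sources used here. Both tables have 28644 rows for 22869 gene symbols, with 1 column per library, and 0 columns of per-sample values could not be matched to a sample. An extra column with the heading Best, for which no description was found, was not used. Rows of the same gene repeat most of the same reads: in genes with several rows and a mean count of at least 50, the lowest row mean was 0.991 of the highest (median). In 41 rows a spreadsheet date stood in place of the symbol, and these were renamed by transcript through the reference gene table of the mouse assembly GRCm38.p6. That table was used only for names and for the class of chromosome (autosome, X or Y), since its build differs from that of the files; 28039 rows matched it by transcript, 419 by symbol and 186 not at all. The deposited FPKM were not a fixed rescaling of the counts, since the ratio of counts to FPKM, taken relative to control 1, had an SD across transcripts of 7.5% of its mean (median over the other libraries; transcripts with over 500 counts in every library).

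The counts as deposited were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, with its default filter on low counts, TMM normalization, no covariate and 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 19353 rows (14572 genes) tested, and a gene was called where 1 of its rows had an adjusted p under 0.05. An edgeR adjusted p below always means this test with Benjamini-Hochberg adjustment. Fold changes are mutant over control, and their standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM (counts scaled to library size after TMM normalization), given as mean ± SD over 3 controls and 2 mutants. Where a group held 1 to 3 counts in all, the ratio of the groups is given with an exact binomial 95% interval, and where it held 0 the fold is a lower bound against a floor of 3 counts over the group. Such intervals and bounds cover counting error only, and amplified reads are not independent molecules.

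Before the data were examined, 27 gene lists with 684 entries were fixed, of which 678 were found in the table. They covered the DNA methylation machinery, mitosis and proliferation, DNA replication, p53 targets, DNA damage repair, CDK inhibitors, apoptosis regulators, intestinal stem and progenitor cells, the Notch pathway, absorptive enterocytes, neonatal endocytic enterocytes, goblet, Paneth, enteroendocrine and tuft cells, epithelial identity, mesenchyme and smooth muscle, endothelium, immune cells, enteric neurons and glia, erythroid cells, imprinted genes, germline genes silenced by methylation, the interferon response, fetal and regenerative epithelium, immediate early and heat shock genes, and cytosolic ribosomal proteins. A gene with several rows was represented by the row with the highest mean count. For each list the calls over all genes, the calls adjusted over the list alone, the median log2 fold change and the camera test of limma 3.58.1 were computed. Camera compares a list with all other genes; it was run on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with an estimated correlation. The fry test, which asks whether the genes of a list move one way on balance and compares them with no other genes, was run beside it. Adjusted p-values of camera and fry are over the 27 lists.

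The genes named with full values follow a rule fixed at the same time. It takes Dnmt1 and Mki67, the 8 largest rises and 8 largest falls among rows with an edgeR adjusted p under 0.05, an average log2 CPM of at least 3 and both mutants on the same side of all controls (1 row per symbol, passing over predicted genes), and the 2 members with the smallest p in each list. Other list members are named only to spell out a small count or as examples, after their values were seen. A few genes that the rule takes are not reported here.

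Alternatives chosen at the same time were RLE and upper-quartile normalization, no filter on low counts, a filter of a CPM of at least 5 in 2 libraries, DESeq2 1.42.0, the edgeR exact test, limma-voom, and limma with a trend on log2(FPKM + 1), on log2(FPKM + 0.1), and on log2(FPKM + 1) of rows with a mean FPKM of at least 1. Further ones were counts summed per symbol, a minimum absolute log2 fold change of 1, an adjusted p under 0.1, and leaving out each library in turn. The tests of 1 row per symbol and of autosomal genes alone were added after the data had been seen. The edgeR test was tested on simulated data, in which counts for the 19353 rows were drawn from the means and spreads of these libraries. Each row was drawn independently, unlike the real rows of the same gene, and 200 rows were changed. After the filter on low counts 19111 rows were tested. Among these the test recovered 61 of 100 transcripts changed 2-fold and 87 of 98 changed 4-fold, with 13 false calls among 161. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.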

Results

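RNA was sequenced from intervillus cells captured from the proximal jejunum of newborn mice, in 3 control libraries and 2 libraries from mice lacking Dnmt1 in the gut epithelium. Dnmt1 is the maintenance methyltransferase, which copies DNA methylation to the new strand after replication. The design compares Ki67-negative intervillus areas of the mutants with Ki67-positive areas of the controls. Loss of Dnmt1 and this choice of areas therefore go together in every comparison below and cannot be told apart. Counted with 1 row per gene, the controls held 13356901, 13101286 and 10530200 reads and mutants 4 and 6 held 8730268 and 10260760. The controls had 17466, 17791 and 18631 genes with at least 1 count and the mutants 17517 and 16931. No pair of libraries of the same group agreed within sampling noise: the chi-square per gene between them was 9.94 to 25.2, where about 1 would be sampling noise. Across genes, log2 CPM correlated at 0.974 to 0.982 between controls, at 0.974 between the mutants, and at 0.936 to 0.951 between a control and a mutant; genes are not independent replicates. Nothing in the labels says that each library came from a separate mouse, so p-values measure only the spread between these libraries, which may be technical.

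Dnmt1, the targeted gene, fell in both mutants. Its level was 115 ± 17.8 CPM in controls (SD, n = 3) and 39.1 ± 1.93 CPM in mutants (SD, n = 2), a log2 fold change of -1.56 ± 0.16 (SE; edgeR adjusted p = 3.74e-05). Its counts were 2240, 2163 and 1351 in the controls and 427 and 525 in the mutants, so the groups did not overlap. Mutant areas were Ki67-negative and control areas Ki67-positive, so the fall is not independent of that choice and is no check of genotype alone. On the deposited FPKM, as log2(FPKM + 1), the fall was -1.49 and missed the threshold (limma adjusted p = 0.105). Which part of Dnmt1 the floxed allele removes is not given in the sources used here, and the count covers the whole transcript. Mki67, the gene of the Ki67 protein, was 907 ± 125 CPM in controls and 508 ± 3.04 CPM in mutants, a log2 fold change of -0.84 ± 0.15 (edgeR adjusted p = 0.00284). The areas were chosen on Ki67 staining, so this fall is no finding, and the mutant areas still held Mki67 transcripts.

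Among transcripts with an average log2 CPM of at least 3, the strongest rises in the mutants included genes normally active in germ cells and Xist, the RNA that coats the inactive X chromosome; the strongest falls were of genes on the Y chromosome, followed by Rpl29. In all, 899 genes rose (1176 transcripts) and 615 fell (809 transcripts). The rises were larger: the median log2 fold change was 1.17 in genes called higher and -0.77 in genes called lower, and 523 genes rose but 155 fell by at least 1 log2 unit. In 3166 genes both mutants lay above all controls and in 3183 below them, together 43.6% of the 14572 genes, where chance gives 20%. At an unadjusted p under 0.05 there were 3794 genes. The count of higher genes was 543 without control 1, 411 without mutant 4 and 550 without mutant 6, and that of lower genes was 254, 171 and 213. With the deposited FPKM in place of counts, between 100 and 262 genes rose and between 14 and 138 fell, and the share of calls that were rises went from 59.4% to between 65.5% and 87.7%.

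**Figure D1:**
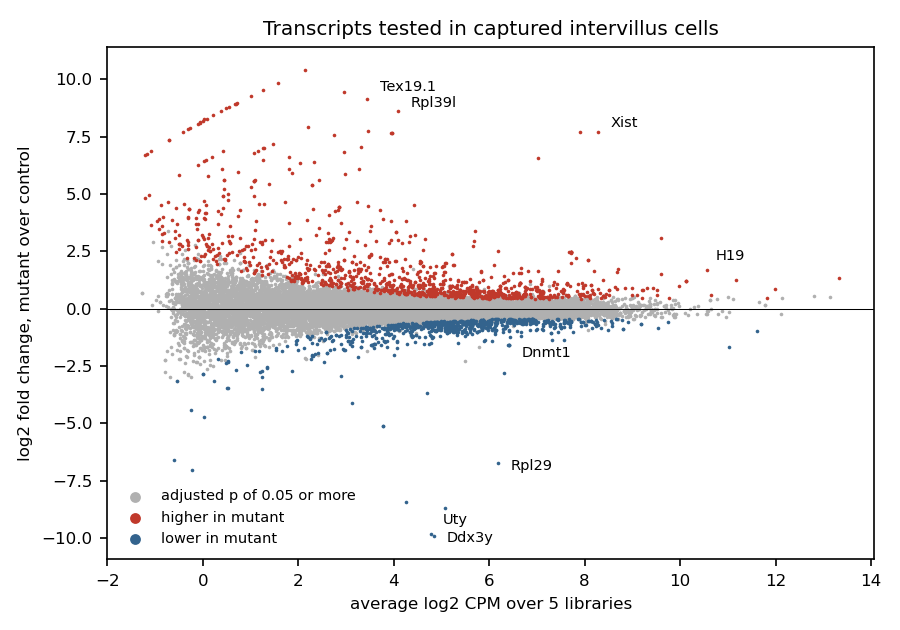
Average log2 CPM over the 5 libraries (x axis) against the log2 fold change of mutant over control (y axis), 1 point per transcript tested, with transcripts called higher in red, called lower in blue and others in grey. The labelled transcripts include Xist at 7.72, Rpl29 at -6.74 and Dnmt1 at -1.56.

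Sex-linked transcripts separated the groups completely. Xist was 3.62 ± 0.652 CPM in controls and 770 ± 185 CPM in mutants, a log2 fold change of 7.72 ± 0.21 (edgeR adjusted p = 1.38e-10). The 4 Y-linked genes tested, Ddx3y, Eif2s3y, Kdm5d and Uty, together had 3160, 2900 and 2710 counts in the controls but 4 and 3 counts in the mutants, and all 4 fell. By counts, Ddx3y was 1139 times as high in controls as in mutants (95% interval 204 to 45000), Uty 1088 times (195 to 42990), Eif2s3y 446 times (153 to 2166) and Kdm5d 377 times (104 to 3114). Every difference between genotypes below is therefore also a difference between libraries with and libraries without Y-linked transcripts. Of X-linked genes, 36 of 491 rose (7.33%) and 26 fell (5.30%), and of autosomal genes 857 of 14019 rose (6.11%) and 582 fell (4.15%). The odds of a rise on the X over autosomes were 1.22 (95% interval 0.835 to 1.72; Fisher's exact test, adjusted p = 0.253) and of a fall 1.29 (0.827 to 1.94; adjusted p = 0.253).

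**Figure D2:**
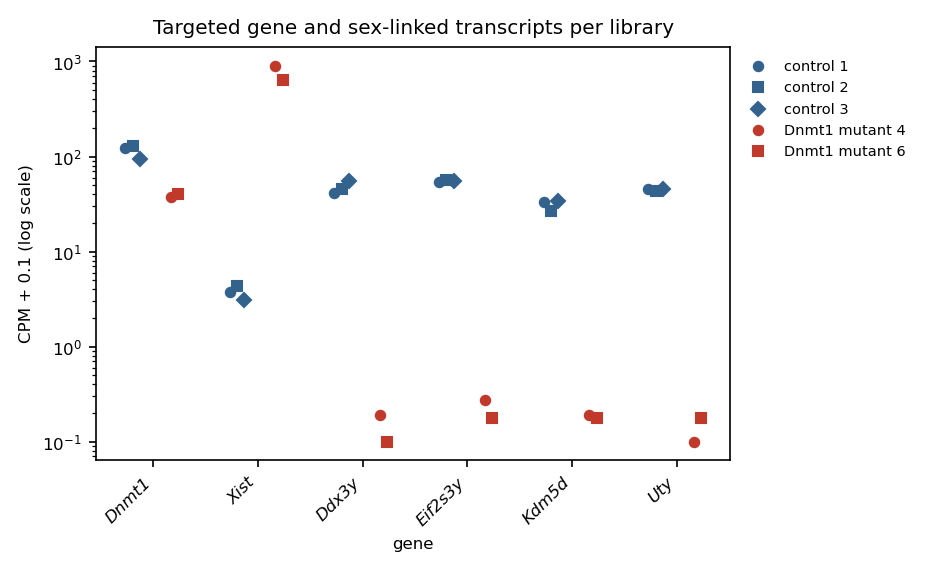
CPM + 0.1 on a log scale (y axis) of Dnmt1, Xist and 4 Y-linked genes (x axis), with 1 point per library, controls in blue and mutants in red. Dnmt1 is lower and Xist higher in both mutants than in every control, and the Y-linked genes are near 0 in both mutants.

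Among well expressed transcripts the largest rises included Xist and were led by Tex19.1, a germline and placental gene, with 2 counts in all controls and 675 in the mutants, 685 times as high in CPM (95% interval 189 to 5670). Rpl39l, a testis-enriched copy of a ribosomal protein gene, was 0.0996 ± 0.0256 CPM in controls and 43.4 ± 4.54 CPM in mutants (log2 fold change 8.63 ± 0.31; edgeR adjusted p = 1.61e-09). Tex19.2, a close copy of Tex19.1 with which it may share reads, rose by 7.75 ± 0.41 log2 units, the X-linked Fmr1nb by 7.68 ± 0.37, the germline gene Asz1 by 7.05 ± 0.47 and Ccdc46 by 4.66 ± 0.37. Rpl29, which encodes a ribosomal protein and has many processed copies in the genome, fell from 120 ± 39.6 CPM to 1.12 ± 0.166 CPM (log2 fold change -6.74 ± 0.34; edgeR adjusted p = 2.81e-08). Gsdmc2 of the gasdermin family fell by 5.13 ± 0.89 log2 units, with counts of 519, 554 and 49 in the controls and 2 and 13 in the mutants. Reg1, a regenerating islet-derived lectin gene, fell by 2.82 ± 0.38 and Cth, an enzyme of cysteine synthesis, by 2.10 ± 0.48. Without mutant 4 the fall of Cth no longer passed the test.

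Many listed germline genes that DNA methylation keeps silent in other tissues rose. The list had 41 members, of which 40 were found and 27 passed the filter on low counts. It includes Xist, which is not a germline gene and which split the libraries in the same way as the Y-linked genes. Xist is therefore part of the counts, the median and the list tests below. Members with few counts in every library were left out, and those at 0 in controls passed only through the mutants. The share that rose and the median therefore depend on this filter. With no filter on low counts 20 rose and 1 fell. Of 27 members measured, 18 rose and 9 did not pass the test (20 rose and 1, Piwil2, fell adjusted over the list alone; 1 also fell over all genes without control 1). Outside Xist and Tex19.1, Dazl, an RNA-binding protein of germ cells, went from 2 counts in all controls to 151 in the mutants, 153 times as high in CPM (95% interval 41.7 to 1277). Slc25a31, the germ cell ADP/ATP carrier, had 0 counts in controls and was at least 69.7-fold higher. The median log2 fold change was 5.46, or 5.37 with the 4 members at 0 in controls set at their lower bound, and camera placed the list above other genes (adjusted p = 2.23e-16; adjusted p = 0.204 with an estimated correlation). The fry test for movement in 1 direction gave an adjusted p of 0.00261. With the filter of a CPM of at least 5 in 2 libraries, 8 members rose, and on the deposited FPKM (pseudocount 1, pseudocount 0.1, and mean of at least 1) 11, 12 and 9. Of the 22 autosomal members 13 rose, and all 5 X-linked members rose (Xist, Tex13, Rhox2a, Rhox6 and Taf7l). Sycp3, a part of the meiotic chromosome axis, was already at 132 ± 44.1 CPM in controls and was 156 ± 58.4 CPM in mutants (edgeR adjusted p = 0.57).

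**Figure D3:**
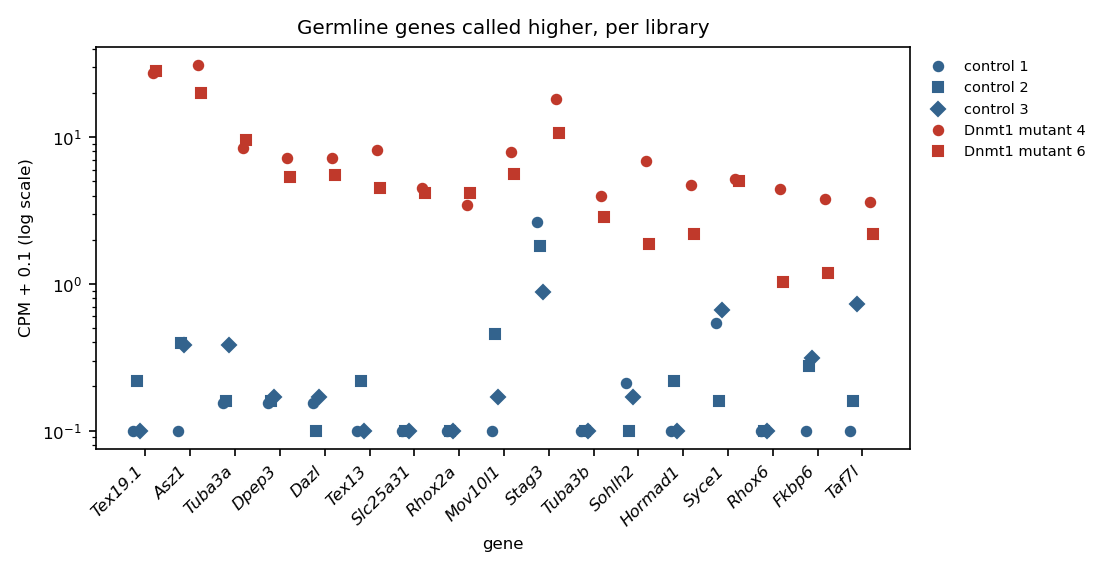
CPM + 0.1 on a log scale (y axis) of the germline genes called higher other than Xist (x axis), with 1 point per library, controls in blue and mutants in red. Both mutants lie above every control in each of these genes, and points at the foot of the axis are libraries with 0 counts.

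Some imprinted genes, which are expressed by parent of origin, also rose. Of 34 measured, 6 rose and 28 did not pass (11 rose and 1, Grb10, fell adjusted over the list alone; 1 also fell over all genes without control 3, and with no filter on low counts 10 rose and 1 fell). H19, a noncoding RNA of the Igf2 domain, rose from 799 ± 199 to 2582 ± 821 CPM (log2 fold change 1.69 ± 0.21; edgeR adjusted p = 0.000195), and Plagl1, a zinc finger transcription factor, from 115 ± 24.4 to 233 ± 1.77 CPM (1.02 ± 0.16). The others were Meg3, H13, Rian and Dlk1. The median was 0.27 and camera placed the list above other genes (adjusted p = 0.0125; adjusted p = 0.311 with an estimated correlation); without control 2 the camera adjusted p was 0.0622. In the same libraries 10 of 27 mesenchyme and smooth muscle markers rose (median 0.53), and the medians of the endothelial, immune and neural lists were 0.33, 0.34 and 0.54. Of 20 genes of the DNA methylation machinery, 3 fell, namely Dnmt1, the demethylating oxidase Tet3 and the DNMT1 cofactor Uhrf1, and the methyl-CpG binding gene Zbtb4 rose (3 and 1 adjusted over the list alone). Tet3 was 163 ± 25.4 CPM in controls and 104 ± 2.83 CPM in mutants (-0.65 ± 0.15). Without control 1, mutant 4 or mutant 6 the fall of Tet3 no longer passed the test and 1 gene of the list fell, and the rise of Zbtb4 was lost without any 1 of the 5 libraries. The de novo methyltransferases Dnmt3a (log2 fold change 0.01 ± 0.13) and Dnmt3b (0.08 ± 0.20) did not pass. Falls in this list, those of Dnmt1 and Uhrf1 among them, are not independent of the choice of areas by Ki67. The list had a median of -0.16 and a camera adjusted p of 0.0443 (adjusted p = 0.311 with an estimated correlation), which was lost without control 1, control 2, mutant 4 or mutant 6 (0.0553, 0.0802, 0.0573 and 0.0889).

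Most mitosis genes fell. Of 30 measured, 23 fell and 7 did not pass over all genes (all 30 fell adjusted over the list alone), with a median of -0.82. Ccnb2, a mitotic cyclin, fell from 88.3 ± 5.40 to 40.7 ± 3.01 CPM (-1.12 ± 0.14; edgeR adjusted p = 0.000198) and Kif11, a spindle motor, from 156 ± 8.07 to 80.9 ± 0.113 CPM (-0.95 ± 0.13; edgeR adjusted p = 0.000421). Camera placed the list below other genes (adjusted p = 2.23e-16; adjusted p = 0.253 with an estimated correlation). Of 36 DNA replication genes 8 fell and 1, the helicase subunit Mcm2, rose (10 and 1 adjusted over the list alone), with a median of -0.38 and a camera adjusted p of 1.32e-05 (adjusted p = 0.442 with an estimated correlation). Mcm10, a replication initiation factor, fell by 0.85 ± 0.17 and Tk1, thymidine kinase, by 0.71 ± 0.17. Neither list is independent of the choice of areas by Ki67. The falls in mitosis genes numbered 13 without mutant 4, 15 without mutant 6 and 3, 5 and 12 on the deposited FPKM (pseudocount 1, pseudocount 0.1, and mean of at least 1). Those in replication genes numbered 0 and 1 without these mutants and 2, 4 and 15 without control 1, 2 and 3; at an unadjusted p under 0.05 there were 18 replication genes. A single rise in the replication list was left without control 1, and none without any other library. Mcm10 no longer passed without either mutant, nor Tk1 without control 1 or mutant 4.

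Among 36 DNA damage repair genes 3 fell and 33 did not pass (2 fell adjusted over the list alone). They included H2afx, a histone marked at DNA breaks, from 107 ± 1.15 to 54.2 ± 1.24 CPM (-0.98 ± 0.13; edgeR adjusted p = 0.0003), and Rad54b. The median was -0.40 and 33 of the 36 had a negative log2 fold change; the camera adjusted p was 1.11e-05 (adjusted p = 0.344 with an estimated correlation). The number of falls was 1 without control 1, control 2 or mutant 6 and 8 without control 3. Mutant areas were Ki67-negative and control areas Ki67-positive, so this list is not independent of that choice.

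Some targets of p53, the transcription factor of the DNA damage response, rose. Of 31 measured, 11 rose and 20 did not pass (14 rose and 1, Gtse1, fell adjusted over the list alone). Genes of cell cycle arrest in this list and among the CDK inhibitors are not independent of the choice of areas by Ki67. Ccng1, a p53-induced cyclin, rose from 110 ± 7.90 to 244 ± 5.42 CPM (1.15 ± 0.13; edgeR adjusted p = 6.71e-05) and Psrc1 from 3.97 ± 0.751 to 16.2 ± 3.42 CPM (2.03 ± 0.26; edgeR adjusted p = 0.000277). Zmat3, Trp53inp1, Eda2r, Plk3, Phlda3 and Gdf15 rose too, while Mdm2, the negative regulator of p53, was 67.3 ± 9.48 and 77.8 ± 1.51 CPM (edgeR adjusted p = 0.383). The median was 0.47 and the camera adjusted p 1.11e-05 (adjusted p = 0.204 with an estimated correlation); 5 members rose without mutant 4, 2, 3 and 4 on the deposited FPKM, and 1 fell without control 3. Of 5 CDK inhibitors, Cdkn1a, which encodes p21, rose from 38.0 ± 8.30 to 90.0 ± 4.08 CPM (1.25 ± 0.17; edgeR adjusted p = 0.000359). Cdkn2b was 29.7 ± 4.57 and 43.5 ± 3.32 CPM (edgeR adjusted p = 0.0509), and these 2 passed adjusted over the list alone. Over all genes Cdkn2b passed without control 3. In this list 2 members rose with RLE or upper-quartile normalization, with no filter or the stricter filter, and with DESeq2, the exact test or limma-voom. The camera adjusted p was 0.107 with a median of 0.55, and 0.0455 without control 3. Of 26 apoptosis regulators the pro-apoptotic Pmaip1 (1.23 ± 0.21), Bax (0.70 ± 0.13) and Bmf rose and the executioner caspase Casp6 fell (3 and 1 adjusted over the list alone). The median was -0.0042 but the mean 0.12, and camera pointed up (adjusted p = 0.679); 1 member rose without mutant 4, Bax among those lost, and the fall of a single member was lost without control 1 or either mutant.

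Few stem and progenitor markers passed the test. Of 28 measured, 1 rose and 2 fell (1 and 2 adjusted over the list alone), against 7 and 2 with no filter on low counts. Prom1 fell from 71.0 ± 14.2 to 37.9 ± 7.39 CPM (-0.91 ± 0.18; edgeR adjusted p = 0.007), Smoc2 also fell, and Cd44, a Wnt-responsive adhesion receptor, rose from 52.8 ± 7.55 to 90.0 ± 24.8 CPM (0.77 ± 0.17; edgeR adjusted p = 0.0125). The crypt base stem cell marker Lgr5 was 36.0 ± 16.4 and 42.6 ± 9.24 CPM (edgeR adjusted p = 0.661) and Olfm4 136 ± 28.0 and 108 ± 9.93 CPM (0.225). The median was 0.10 and the camera adjusted p 0.748; the median was -0.07 without control 3 and -0.02 without mutant 4. Prom1 no longer passed without mutant 6, nor Cd44 without control 1 or mutant 4; 2 members rose without control 2 or mutant 6, 1 fell without control 1, control 2 or mutant 4, and both falls were lost without mutant 6. Of 17 Notch pathway genes 0 passed the edgeR test, over all genes or adjusted over the list alone, and 0 passed with DESeq2, the edgeR exact test or limma-voom; 1 fell with no filter on low counts, and 2 had an unadjusted p under 0.05. Mib1 was nearest, at 49.3 ± 5.15 and 37.4 ± 1.97 CPM (edgeR adjusted p = 0.111), and Nrarp was 28.8 ± 3.14 and 19.4 ± 8.79 CPM and passed without mutant 6. The median was -0.12 and the camera adjusted p 0.673.

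Some markers of absorptive enterocytes, the nutrient-absorbing cells of the villus, rose. Of 40 measured, 15 rose and 2 fell (22 and 2 adjusted over the list alone). Mutant areas were taken as Ki67-negative and control areas as Ki67-positive, so markers of differentiated cells, here and in the next lists, are not independent of that choice. Krt20, a keratin of differentiated cells, rose to 164 ± 0.715 CPM (log2 fold change 1.57 ± 0.17; edgeR adjusted p = 5.13e-05) and Sis, sucrase-isomaltase, from 5.98 ± 0.488 to 26.6 ± 8.34 CPM (2.15 ± 0.23; edgeR adjusted p = 6.04e-05). The apolipoprotein genes Apoc3, Apoa4 and Apoa1 rose, while the chloride exchanger Slc26a3 and the maltase Mgam fell, and the lactase gene Lct was 974 ± 242 and 1066 ± 80.5 CPM (edgeR adjusted p = 0.701). The median was 0.47 and the camera adjusted p 1.12e-05 (adjusted p = 0.344 with an estimated correlation); without mutant 4, 9 rose and the falls were lost, and without mutant 6, 1 fell. On the deposited FPKM (pseudocount 1, pseudocount 0.1, and mean of at least 1) 0, 1 and 6 rose and 0, 0 and 1 fell, against 18 and 2 with DESeq2 and 24 at an unadjusted edgeR p under 0.05. Of 18 genes of neonatal endocytic enterocytes, which take up milk proteins, 7 rose and 1, the urea cycle enzyme Cps1, fell (14 and 3 adjusted over the list alone). The endocytic receptor Lrp2 rose from 1.37 ± 0.336 to 13.6 ± 4.35 CPM (3.31 ± 0.33; edgeR adjusted p = 3.48e-05) and Ctsl, a lysosomal protease, from 96.3 ± 50.7 to 380 ± 23.2 CPM (1.98 ± 0.28; edgeR adjusted p = 0.000564). The median was 0.51 and the camera adjusted p 0.000705 (adjusted p = 0.344 with an estimated correlation); 4 rose without mutant 4, 3 without mutant 6 and 12 without control 2, and 3 fell without control 3 and 2 without mutant 6.

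Secretory lineages were counted list by list, and no difference between them was tested. Of 13 Paneth cell genes 5 rose and 8 did not pass (6 rose and 1, Reg3b, fell adjusted over the list alone; 1 also fell over all genes without control 3). They were Lyz1, lysozyme, from 13.9 ± 6.13 to 107 ± 10.4 CPM (2.93 ± 0.27; edgeR adjusted p = 1.51e-05), Ang4, an antimicrobial ribonuclease, from 8.73 ± 1.46 to 24.5 ± 2.19 CPM (1.48 ± 0.21; edgeR adjusted p = 0.000521), Pla2g2a, Reg4 and Guca2b. The median was 0.45 and the camera adjusted p 0.0191 (adjusted p = 0.344 with an estimated correlation). Without mutant 4 the median was 0.13 (adjusted p = 0.0747), without mutant 6 0.80 and without control 2 0.70. Of 18 goblet cell genes Retnlb rose from 0.730 ± 0.453 to 3.42 ± 0.952 CPM and Capn9 fell from 3.27 ± 1.42 to 0.497 ± 0.048 CPM (2 higher and 6 lower adjusted over the list alone; median -0.09, camera adjusted p = 0.404). Neither passed without mutant 4 or without mutant 6, nor Retnlb without control 1, and 3 members fell without control 2. Of 26 enteroendocrine genes the hormone genes Sct (1.28 ± 0.18), Cck (0.95 ± 0.17) and Sst and the granule gene Chga rose, and Scgn fell (5 and 2 adjusted over the list alone). Log2 fold changes were positive in 15 members of this list and negative in 11. Those 11 included the transcription factor gene Neurog3 (-2.09 ± 0.63, edgeR adjusted p = 0.0507) and the hormone gene Gcg (-0.98 ± 0.43, edgeR adjusted p = 0.165). The median was 0.17 but the mean -0.04, and camera pointed up (adjusted p = 0.926); 1 member rose without mutant 4, Cck among those lost, the fall of Scgn was lost without control 1 or mutant 4, and 2 fell without control 2 or mutant 6. Of 7 tuft cell genes 1 rose, the prostaglandin D synthase Hpgds, from 12.9 ± 2.88 to 36.7 ± 2.11 CPM (1.51 ± 0.20; 1 adjusted over the list alone), and Plcb2 was 5.69 ± 1.15 and 8.37 ± 2.67 CPM. The tuft cell median was 0.34 with a camera adjusted p of 0.0748, which fell below 0.05 without control 1, control 2, mutant 4 or mutant 6 (0.0433, 0.0495, 0.0191 and 0.0108).

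Some markers of mesenchyme, immune cells and enteric neurons and glia rose in the mutants, as did 1 endothelial marker. None of the 9 erythroid genes passed as higher, and several epithelial transcription factors fell. Differences between these lists in the number of calls were not tested. Of 27 mesenchyme and smooth muscle genes 10 rose and 17 did not pass (20 rose adjusted over the list alone), with a median of 0.53 and a camera adjusted p of 1.71e-07 (adjusted p = 0.311 with an estimated correlation). The matrix gene Postn rose from 53.9 ± 3.70 to 108 ± 7.14 CPM (1.00 ± 0.13; edgeR adjusted p = 0.000293) and the collagen gene Col1a2 from 241 ± 9.17 to 375 ± 1.54 CPM (0.64 ± 0.12; edgeR adjusted p = 0.00512). In the list 1 gene rose without mutant 4 and 4 without control 1, none did on the deposited FPKM (14 with DESeq2, 22 at an unadjusted edgeR p under 0.05), and Col1a2 no longer passed without either mutant. Of 17 endothelial genes Plvap rose (0.61 ± 0.17; 1 adjusted over the list alone; not without control 1, mutant 4 or mutant 6), Cdh5 had a log2 fold change of 0.41 ± 0.15 (edgeR adjusted p = 0.0954), and the median was 0.33 (camera adjusted p = 0.00278; adjusted p = 0.311 with an estimated correlation). Of 20 immune cell genes the macrophage genes Csf1r (1.54 ± 0.18) and Mrc1 (1.37 ± 0.18) rose (2 adjusted over the list alone; 1 other fell without mutant 6), with a median of 0.34 (camera adjusted p = 0.00201; adjusted p = 0.311 with an estimated correlation). Of 12 genes of enteric neurons and glia the glial S100b (1.77 ± 0.20), Prph and Uchl1 rose (5 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00204; adjusted p = 0.272 with an estimated correlation) and of 1.01 without control 2; 1 rose without mutant 4, and Prph, with 4 counts in the controls and 44 in the mutants, did not pass without mutant 4. Of 9 erythroid genes the X-linked heme synthesis gene Alas2 fell (-1.02 ± 0.30; 1 adjusted over the list alone), a call lost without any 1 of the 5 libraries. Hba-a1 was 17.0 ± 1.45 and 22.4 ± 0.301 CPM, and the list median was 0.15 but its mean -0.08, and camera pointed up (adjusted p = 0.852). Of 22 epithelial identity genes 6 fell and 2 rose (9 and 2 adjusted over the list alone). Klf5 fell by 0.90 ± 0.13, and Cdx2, Esrp1, Gata4, Hnf4g and Grhl2 fell too, while Cldn4, a tight junction gene, rose by 1.88 ± 0.27 and the keratin gene Krt18 also rose. The median was -0.31 (camera adjusted p = 0.0122; adjusted p = 0.312 with an estimated correlation); 2 fell without mutant 6 and 3 without control 1, 1 rose without mutant 4, and the camera adjusted p was 0.0559 without mutant 6.

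Of the remaining lists, some genes of fetal and regenerating epithelium and some immediate early genes rose, in the same libraries as mesenchyme markers (10 of 27 rose, median 0.53) and immune markers (2 of 20, median 0.34). Of 15 fetal and regenerative genes 7 rose and 1, Trp53i11, fell (9 and 1 adjusted over the list alone). Areg, an EGF receptor ligand, rose from 5.29 ± 2.40 to 37.8 ± 2.77 CPM (2.85 ± 0.28; edgeR adjusted p = 3.05e-05), S100a6 from 51.4 ± 7.47 to 150 ± 49.1 CPM (1.54 ± 0.19; edgeR adjusted p = 0.00016), and Clu, Anxa1, Cald1, Ereg and Anxa3 rose too, while Ly6a was 10.7 ± 2.94 and 13.1 ± 0.774 CPM. The median was 0.68 and the camera adjusted p 4.58e-05 (adjusted p = 0.324 with an estimated correlation); 4 rose without control 1 or mutant 4, and without mutant 4 the fall of Trp53i11 was lost. Of 21 immediate early and heat shock genes Egr1 (1.31 ± 0.19), Atf3 (2.24 ± 0.35), Fos and Jun rose and 17 did not pass (4 rose adjusted over the list alone), with a median of 0.36 and a camera adjusted p of 0.000564 (adjusted p = 0.312 with an estimated correlation); 2 rose without mutant 6, and 1 fell without control 3. Of 32 cytosolic ribosomal protein genes Rpl11 (-0.94 ± 0.26) and Rps18 (-0.43 ± 0.13) fell, with 0 adjusted over the list alone and 9 at an unadjusted p under 0.05, a median of -0.24 and a camera adjusted p of 0.000564 (adjusted p = 0.452 with an estimated correlation). With DESeq2 5 fell, and without control 3, 4 fell. Rpl11 was lost on leaving out any 1 of the libraries, as was Rps18 without control 1, control 2 or either mutant. Of 32 interferon response genes 1 fell, Mx2, from 8.30 ± 2.36 to 2.18 ± 0.793 CPM (-1.93 ± 0.38; 1 adjusted over the list alone; not without mutant 6), and Mx1 was 5.02 ± 0.409 and 2.35 ± 0.0522 CPM. The interferon median was 0.07 and camera pointed up (adjusted p = 0.926) but fry down (adjusted p = 0.979), with the mutants apart: the median was -0.30 without mutant 4 (adjusted p = 0.0444) and 0.25 without mutant 6 (adjusted p = 0.0437). It was -0.03 without control 1 and -0.08 without control 2, and 1 member rose without control 2 or mutant 6 and 3 without control 3.

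**Figure D4:**
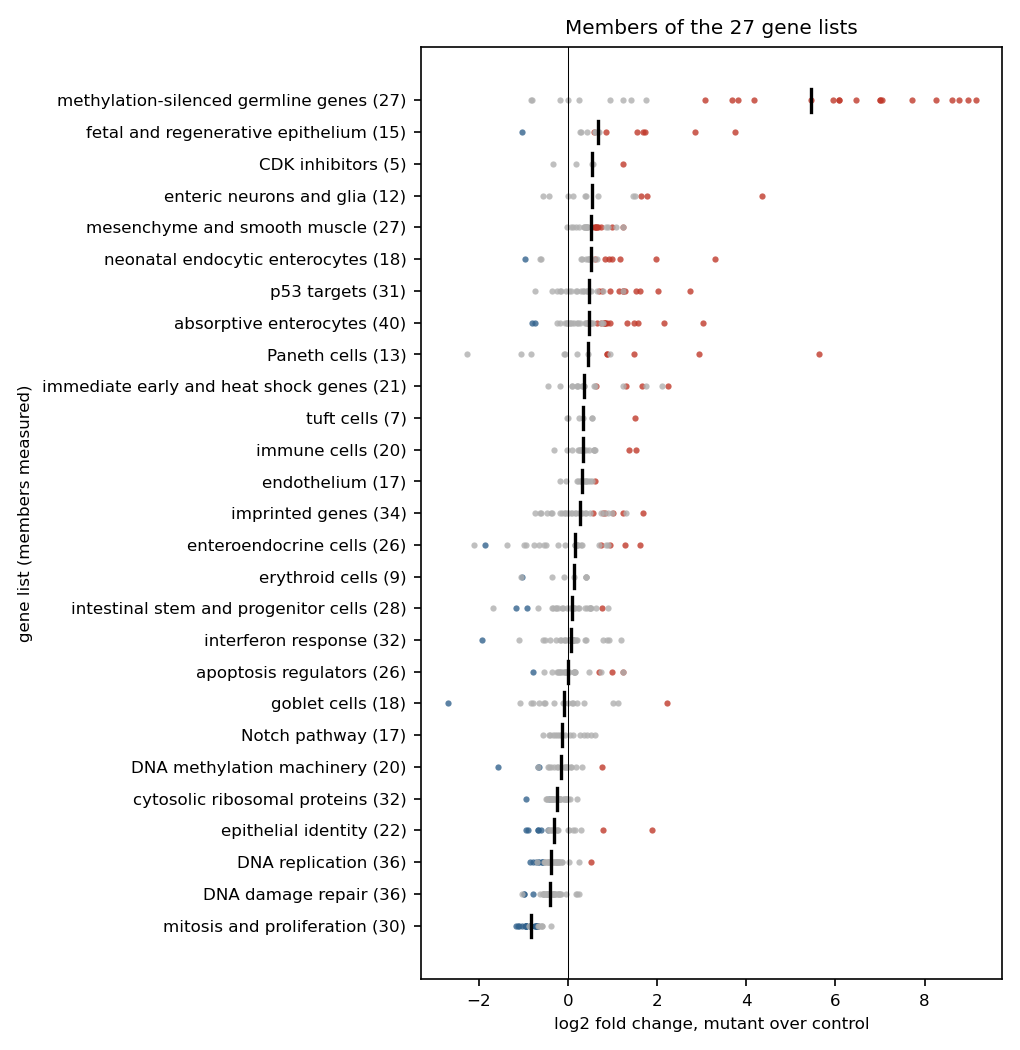
Log2 fold change of mutant over control (x axis) of each measured member of the 27 lists (y axis, with the number measured), where red and blue points passed the test, grey points did not and the black bar is the list's median. Medians run from -0.82 for mitosis and proliferation to 5.46 for germline genes.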

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

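The tests with 1 row per gene symbol and with autosomal genes only were chosen after the data had been seen; the others were not. RLE and upper-quartile normalization, DESeq2, the edgeR exact test, limma-voom, the stricter filter, counts summed per symbol and 1 row per symbol kept the number of genes higher in mutant and of genes lower in mutant within 1.5 times of 899 and 615. DESeq2 called 1045 and 719, of which 875 and 608 were shared with the main calls. Genes lower in mutant numbered 956 with no filter on low counts, where rises numbered 7 among stem and progenitor genes (1 with the filter), 23 among enterocyte genes (15), 11 among endocytic enterocyte genes (7), 17 among mesenchyme genes (10), 10 among imprinted genes (6) and 3 among interferon genes (0), and falls 6 among repair genes (3), 4 among goblet cell genes (1), 3 each among enteroendocrine, endocytic enterocyte and interferon genes (1 each), 2 among Paneth cell genes (0), 5 among ribosomal protein genes (2) and 1 among Notch genes (0). With the FPKM (pseudocount 1, pseudocount 0.1, and mean of at least 1) genes higher in mutant numbered 100, 159 and 262 and genes lower in mutant 14, 37 and 138; 85 and 13 of those with pseudocount 1 were shared with the main calls. In the same order, rises with the FPKM numbered 0, 0 and 1 among endocytic enterocyte genes (7 with counts), 0, 0 and 4 among Paneth cell genes (5), 0, 0 and 3 among imprinted genes (6), 1, 2 and 3 among fetal and regenerative genes (7) and 0, 0 and 3 among immediate early and heat shock genes (4); falls numbered 0, 0 and 1 among replication genes (8) and 1 each among epithelial identity genes (6). Rises with the FPKM also numbered, in that order, 0, 1 and 2 among enteroendocrine genes (4 with counts). They were 0, 1 and 1 both among enteric neuron and glia genes (3) and among apoptosis regulators (3), and falls 1 each among repair genes (3). With an absolute log2 fold change of at least 1, genes higher and lower in mutant numbered 523 and 155, with an adjusted p under 0.1 1352 and 1051, and with each library left out 411 to 1063 and 171 to 653. The share of calls that were rises was 59.4%, against 66.3% with upper-quartile normalization, 64.8% with limma-voom, 87.7%, 81.1% and 65.5% with the FPKM, 70.6% without mutant 4 and 72.1% without mutant 6. No scaling moved the median log2 fold change of all genes by more than 0.1. Leaving out a mutant leaves 1 mutant library, which is then assumed to vary like the others. No paired analysis was possible because the groups share no replicate numbers.

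Dnmt1 fell by 1.49 on log2(FPKM + 1) and missed the threshold there; it passed in every other test, and lay between -1.68 and -1.47 with a library left out. Of the single genes named, 752 comparisons with alternatives kept direction and side of the threshold, 107 kept the direction but missed the threshold, 12 newly passed it, and none turned; with a library left out the numbers were 295, 43 and 2. For gene lists the numbers were 353, 36 and 10 with 6 turned, and with a library left out 112, 7 and 6 with 10 turned. All 18 camera calls were lost with an estimated correlation, among them those at the medians of -0.82 for mitosis, -0.38 for DNA replication, 0.47 for p53 targets, -0.40 for DNA damage repair, 0.47 for absorptive enterocytes, 0.53 for mesenchyme, 0.27 for imprinted genes, 5.46 for germline genes and -0.16 for the DNA methylation machinery. The estimated correlation was below the preset 0.01 for p53 targets (0.00585), the DNA methylation machinery (0.000438) and enteric neurons and glia (-0.0728). A larger correlation between genes therefore does not account for every lost camera call. The fry test missed the threshold for 12 lists that passed with camera, among them DNA replication (-0.38), DNA damage repair (-0.40), absorptive enterocytes (0.47) and imprinted genes (0.27). The list DNA methylation machinery missed the threshold with no filter (-0.23), the stricter filter (-0.14), the FPKM (-0.083, -0.090 and -0.13) and autosomal genes only (-0.16), and ranged from -0.23 to -0.13 with a library left out. The list imprinted genes ranged from 0.19 to 0.38 and the list intestinal stem and progenitor cells from -0.073 to 0.24. The camera direction of the list enteroendocrine cells turned with upper-quartile normalization (0.20), the FPKM with pseudocount 0.1 (0.0080) and counts summed per symbol (0.16); with the stricter filter it kept its direction and passed (0.35), and with a library left out the median ranged from -0.022 to 0.26. That of the list erythroid cells turned with the FPKM with pseudocount 0.1 (-0.11) and ranged from -0.039 to 0.35, and that of the list interferon response turned with the exact test and fry (0.070) and ranged from -0.30 to 0.26. The cause was not tested. Depth limits the genes at 0 in controls, for which only lower bounds are given.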

Other observations

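All tests in this part were chosen after the results had been seen. The gene groups in this and the next paragraph were written down after the called genes had been read, so they are described without a group test and their counts are no independent evidence. Of 26 genes of amino acid supply and the integrated stress response, the programme run by the transcription factor ATF4, 13 rose and 1, Cth, fell, with a median log2 fold change of 0.64. Asns, asparagine synthetase, rose from 30.7 ± 2.21 to 95.6 ± 4.85 CPM (1.64 ± 0.14; edgeR adjusted p = 4.98e-06), and Chac1 (6.34 ± 0.47), Trib3 and the cystine transporter Slc7a11 rose too. Of 14 measured genes of plasma proteins made by liver and yolk sac, 12 rose, with a median of 1.90. They included Leap2, from 93.4 ± 8.90 to 294 ± 12.3 CPM (1.65 ± 0.13), Ttr (2.21 ± 0.36), Afp (1.88 ± 0.31) and Apoh.

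Of 38 lysosomal hydrolase genes 16 rose, with a median of 0.45, among them Ctsh, from 52.3 ± 4.57 to 177 ± 10.6 CPM (1.76 ± 0.13), and Lgmn. The macrophage genes Csf1r (1.54 ± 0.18) and Mrc1 (1.37 ± 0.18) rose in the same libraries, but 18 of the 20 immune cell genes did not pass. Among those were Cd68 (edgeR adjusted p = 0.150), Emr1 (0.474) and C1qa (0.880), and the hydrolase gene Ctss did not pass either (0.429). Genes of neonatal endocytic enterocytes also rose, 7 of 18, and that list shares Ctsl, Neu1 and Glb1 with the hydrolases. Of 25 measured genes of sterol synthesis and fatty acid desaturation 8 fell, with a median of -0.43, including Fads2, from 89.2 ± 26.9 to 33.2 ± 5.65 CPM (-1.43 ± 0.22), and Nsdhl. All 3 measured genes of the gasdermin C cluster fell (median -4.10), though Gsdmc3 and Gsdmc4 overlapped between the groups, and near-identical members of this family can share reads.

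Xist was high and Y-linked transcripts near 0 in both mutants. The summed level of the 4 Y-linked genes in the higher mutant was 0.198% of the control mean, which argues against male mutant cells that had switched Xist on. Together these genes had 3160, 2900 and 2710 counts in the controls and 4 and 3 in the mutants, which argues against groups of the same sex. Female mutants and male controls would give both the Y-linked and the Xist values and stay the candidate explanation. Xist in the lower mutant was 149.9 times the highest control, but that value is part of the pattern itself and so is no test of it, and the labels analysed here give no sex. If the mutants were female, sex goes with genotype in every comparison of these 5 libraries.

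Of the 27 measured members of the germline list, Xist among them, 18 rose, each higher in both mutants than in every control. Of the 22 autosomal members measured 13 rose (median log2 fold change of all 22, 4.00), which argues against X chromosome dosage as the whole cause. Of the 19 autosomal members without a near copy 10 rose (median 3.07), which argues against reads shared with a copy as the whole cause. The medians themselves are no test, because members at 0 in controls passed the filter on low counts only through the mutants. All 5 X-linked members rose (median 7.72), as did the 4 other than Xist (7.63). An effect of sex on autosomal genes cannot be told apart from loss of Dnmt1, because 0% of mutant libraries had Y-linked reads at 50% or more of the control mean and none can therefore serve as a male mutant. Loss of methylation through loss of Dnmt1 may account for the rise, but methylation was not analysed here.

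Some markers of non-epithelial cells rose in the mutants, though none of the erythroid list did. A larger share of such cells might raise the markers of every type alike, but types can also enter captured areas in unequal amounts, which was not tested and which a difference between the lists would not exclude. The first test, on the mesenchyme, endothelium, immune and neural lists, gave a range of list medians of 0.212 (permutation p = 0.2, 10000 permutations), so a common shift could account for those; with the erythroid list added afterwards the range was 0.395, from 0.147 to 0.542 (permutation p = 0.0185). The erythroid list rests on 9 genes with low counts, in which Hba-a1 and Hba-a2 as well as Hbb-b1 and Hbb-b2 carry identical values and Alas2 is X-linked, so a larger share of other cells and an effect of genotype on the captured cells (range 0.395) cannot be told apart. Of the 85 markers, 78 were at 1 CPM or more in controls, and 0 were on another of the lists.

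Rpl29 had 2992, 1763 and 1279 counts in the controls and 14 and 13 in the mutants. Gapdh had 81, 42 and 81 counts in the controls and 44 and 45 in the mutants, against 48156 to 56711 for Actb. Tsix, the antisense partner of Xist, had 21, 40 and 15 counts in the controls and 431 and 308 in the mutants, and reads of the 2 genes cannot be separated if the counting ignored strand.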
